A study of Mus musculus with 22 samples.

How the data were processed

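Chromatin immunoprecipitation with sequencing (ChIP-seq) was run on mouse cells reprogrammed from embryonic fibroblasts of the C57BL/6 strain. Of the 22 samples, 16 have a peak file: 12 histone libraries from 3 induced pluripotent stem (iPS) cell lines and 4 libraries of the HA epitope tag from cells at day 20 of reprogramming. The other 6 are input samples, used by the authors as controls and not analysed on their own here. Cells were fixed with 1.5% formaldehyde, per the labels. For the iPS cell samples the labels also give 100 nM 4-hydroxytamoxifen, which acts on the Oct4-linked MerCreMer recombinase of these cells and so on their fluorescent reporter.

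According to the processing notes in the labels, the authors used CASAVA 1.8.2, Bowtie2 2.2.5, SAMtools 1.3 and DiffBind 1.16.2 with the mm10 genome. Per the file headers, peaks were called in each library against 1 input library with MACS 2.1.0.20150731 for the histone marks and MACS 2.1.1.20160309 for HA, at a q-value of 0.01, a band width of 300 bp, a tag size of 51 bp and at most 1 tag kept per position. In the peak files deposited by the authors, the pileup is a signal (fragments over the summit), the significance is a -log10 p-value and a -log10 q-value, and the fold enrichment is a ratio over the local background. Each of the 6 region tables deposited by the authors covers 4 libraries of 2 groups and gives the signal per library as normalized reads, a log2 fold change, a p-value and an FDR. Region tables use the union of called peaks, and their lowest value is 1 read. Whether control reads were subtracted is not stated in the sources used here. Dividing each library's values by its value of 1 read gave whole numbers for 100% of values within a tolerance of 1e-06. Whole read numbers per region could thus be recovered, net of any control reads that were subtracted.

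Histone C2 and OSKM samples shared a pair of input samples, while C3 had its own pair. Any difference between these inputs therefore goes with the comparison of C3 with the other lines and cannot be separated from it. How replicates were made (separate cultures, clones or repeated immunoprecipitations) is not labelled, so p-values measure the spread between samples. The number of tags kept after duplicate removal in replicates 1 and 2, per the file headers, was 33389033 and 29774623 (H3K27ac, C2), 32802769 and 33760862 (C3) and 29351874 and 28947967 (OSKM). It was 46304808 and 29264090 (H3K9me3, C2), 44426255 and 34550520 (C3) and 35889217 and 36620590 (OSKM). In the HA libraries it was 2506011 and 3896935 in C2 and 1707437 and 1629753 in Empty, of 30141416, 46426379, 25985373 and 26446397 tags, with a redundant share of 0.92 to 0.94. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

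Regions were compared with limma 3.58.1 in R 4.3.3, with a trend on the log2 of the normalized reads plus 1, separately for each pair of lines, and called at a Benjamini-Hochberg adjusted p under 0.05. The R package data.table was at version 1.17.8, and other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. This fit, the lists of genes, the rule for naming genes and the first set of alternative settings were written before the data were examined. Between 12.4% and 24.9% of regions in a table were at 1 read in all 4 libraries, and these distort the variance that limma shares between regions. On simulated data with 200 changed regions, 8.14% to 30.1% of calls of this fit were false. Requiring a call also with the lowest 25% of regions left out, a setting that had itself been written beforehand, brought that share to 3.48% to 13.3%. That requirement was chosen after the data were seen, from the simulations. Counts are given for the planned fit, and "rose", "fell" and "changed" are used only for regions called in both fits. In the planned fit, 4-fold changes were recovered in 66.8% to 88.8% of simulated regions and 2-fold changes in 5.75% to 56.5%. With 2 libraries per group, both libraries of one group lie above both of the other in 33.3% of regions by chance.

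The annotation gives gene extents without strand, so transcription start sites could not be placed. A gene was given the H3K27ac region with the highest mean within 2500 bp of its extent, or the H3K9me3 region with the highest mean within 2000 bp, in place of the planned window at the start site. Of 135566 H3K27ac regions (median width 1001 bp) 68.4% had a gene within 2500 bp, and of 68845 H3K9me3 regions (median width 972 bp) 33.5% did. A fixed set of 16 gene lists (352 names, 350 found in the annotation) and 6 families taken by symbol were tested with camera at a preset correlation of 0.01. The lists were naive and core pluripotency, primed and formative pluripotency, fibroblast and mesenchymal, epithelial, endoderm, trophoblast, neuroectoderm, mesoderm, endothelial and haematopoietic, 2-cell-like, germline, imprinted, H3K9 methylation machinery and readers, housekeeping, cell cycle arrest and senescence, and the transduced factors. Families were zinc finger (Zfp) genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, histone cluster genes and Hox genes. Lists with at least 3 members in a table were tested, 22 for H3K27ac and 19 for H3K9me3. None of the list calls holds when the correlation between genes is estimated from the data, and that p is given beside them. With 2 libraries per group that test has few degrees of freedom and could hardly call any list. Its failure therefore cannot show that correlation between genes accounts for the list calls, which stay unsettled.

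Genes and regions named were, per comparison and direction, the 5 called regions with the largest log2 fold change, at or above the median level and without overlap between the groups, and up to 4 called members of each list. The transduced factors were always named. A few genes picked by this rule are not reported here, though the counts include them. A fold against a group at 1 read in both libraries is given as a lower bound against 3 reads per library. The bound holds for the deposited region values. If control reads were subtracted, a library at 1 read may hold more reads, and the bound does not cover that. HA sites were regions with a peak in both C2 libraries and in neither Empty library, with an overlap of at least 1 bp. Genes were sought within 10000 bp of an HA site. Overlaps of HA sites with histone peaks were compared with Fisher's exact test, two-sided, over peaks and not over replicates.

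Alternative settings written beforehand were a replicate block, a pseudocount of 8, leaving out the lowest 25% of regions, median-centred libraries, quantile normalization, the FDR in the authors' deposited table, other windows and thresholds, stricter peaks, other overlaps and leaving out each library. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood) on the recovered reads, quantile normalization without regions at 1 read in any library, fits without regions at 1 read in all libraries, without regions at 1 read in a library that called a peak there or without chromosomes 8, X and Y, and the same number of strongest HA peaks per library. Median centring moved the median log2 fold change of all H3K27ac regions by -0.39 (C2 against OSKM), -0.33 (C3 against OSKM) and -0.10 (C2 against C3), and that of H3K9me3 regions by 0.0549, 0.0489 and -0.00185 in the same order. Region-level tests between HA groups were not made, since no region table covers them.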

Results

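The study mapped an active histone mark (H3K27ac, found at promoters and enhancers), a repressive histone mark (H3K9me3, found in heterochromatin) and the binding of HA-tagged artificial transcription factors in mouse cells on the way to pluripotency. Oct4 is a core factor of the pluripotent state, and the classical reprogramming mix (OSKM) joins it to Sox2, Klf4 and c-Myc. In the C2 and C3 lines, Oct4 was replaced by 3 zinc-finger artificial factors, of which the lines share a pair and differ in the third. The histone marks were measured in iPS cells of the C2, C3 and OSKM lines, with 2 libraries per line and mark. Factor set goes with line, so a difference between lines cannot be assigned to the artificial factors or to the lack of Oct4. The HA tag was measured in C2 cells at day 20 and in cells given an empty vector (Empty), again with 2 libraries each, to show where the artificial factors sat before reprogramming was complete. The Empty cells measure the background of the antibody.

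Reads in regions ranged from 7033486 to 17649231 per library over the 135566 regions of H3K27ac and from 3412599 to 8548902 over the 68845 regions of H3K9me3. In H3K27ac, regions with a peak in both libraries numbered 52048 in C2, 73204 in C3 and 62585 in OSKM. Peaks of C3 overlapped 92.5% of the C2 regions and peaks of OSKM overlapped 84.4% of them. In H3K9me3 the numbers were 36732 in C2, 35925 in C3 and 57821 in OSKM. OSKM peaks overlapped 97.0% of the C2 regions and 93.8% of the C3 regions, whereas C2 peaks overlapped 49.3% of the OSKM regions. The libraries of a line differed in their own peaks: 47.5% of the 116945 H3K27ac peaks of C2 replicate 1 were overlapped by replicate 2, against 91.1% the other way, and 41.0% of the 96055 H3K9me3 peaks of C3 replicate 1, against 95.0% the other way. Averaged over the libraries of a group, 68.0% to 81.4% of peaks were overlapped by the other replicate in the histone groups, and 27.3% and 16.5% in the HA groups.

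Chromosome 8 stood apart in OSKM, with more of both marks along its length than in C2 and C3. It held 7.61% and 7.48% of the H3K27ac reads of the OSKM libraries, but 4.15% and 3.46% in C2 and 4.29% and 3.84% in C3. For H3K9me3 the shares were 6.14% and 5.99% in OSKM, 3.61% and 3.86% in C2, and 4.25% and 4.06% in C3. The median log2 fold change of the stronger chromosome 8 regions was -1.33 (C2) and -1.04 (C3) against OSKM in H3K27ac, beside -0.15 and -0.03 over all chromosomes other than 8, X and Y. The same medians in H3K9me3 were -0.95 and -0.79, beside -0.15 and -0.05. Chromosome Y stood apart in C2: it held 0.105% and 0.116% of the H3K9me3 reads of the C2 libraries, against 0.430% and 0.454% in C3 and 0.453% and 0.432% in OSKM. Since chromosome 8 carries several genes of the lists, counts are also given without it and the sex chromosomes.

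**Figure D1:**
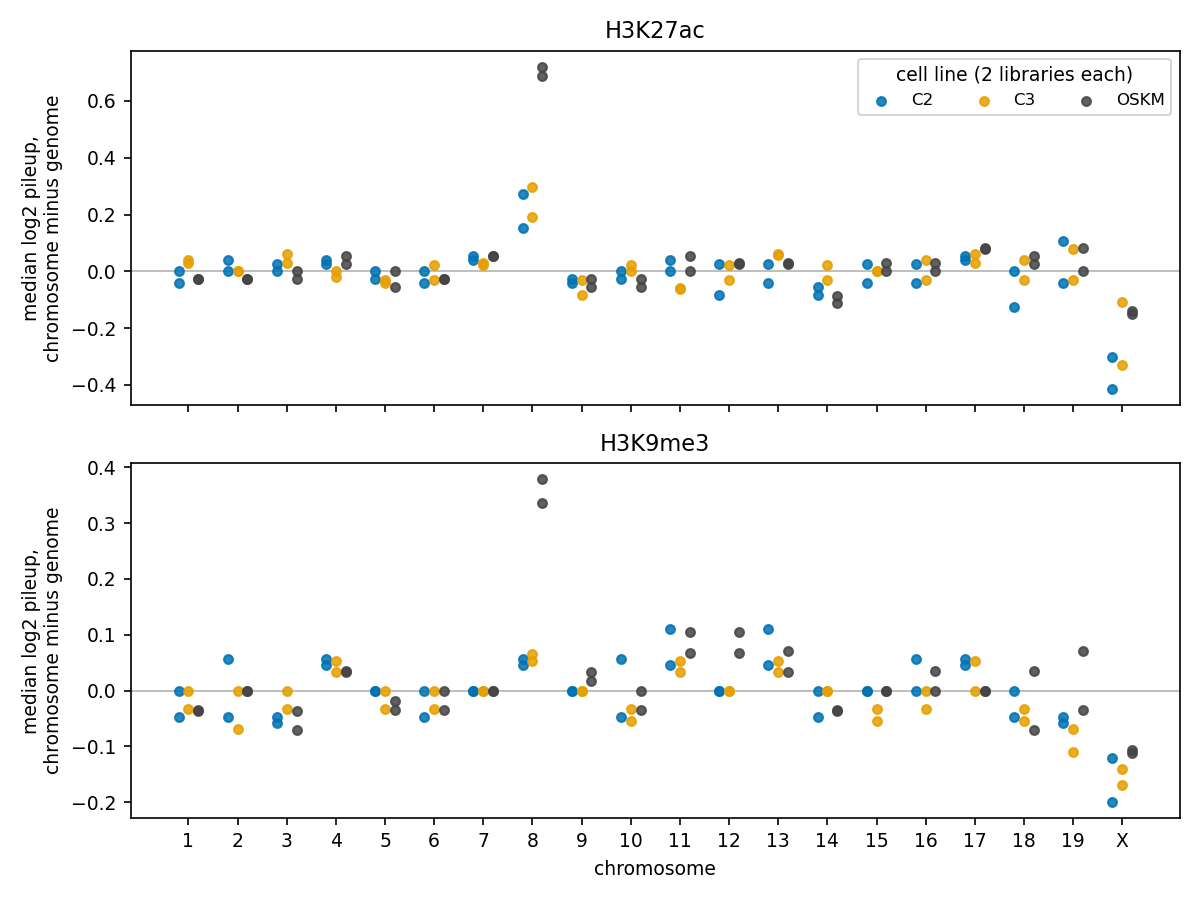
Median log2 pileup of peaks on each chromosome minus that of the whole genome (vertical axis, log2), by chromosome (horizontal axis), for H3K27ac (top) and H3K9me3 (bottom); each point is 1 library of C2, C3 or OSKM. On chromosome 8 the OSKM libraries sit at 0.72 and 0.69 in H3K27ac and at 0.38 and 0.34 in H3K9me3, above the C2 and C3 libraries.

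The first comparison asks how the H3K27ac landscape of C2 iPS cells, made without Oct4, differs from that of OSKM iPS cells. The region with the largest loss was a stretch of chromosome 12 (109521366 to 109534179, at the predicted gene Gm34081), where H3K27ac was 2525 ± 149 normalized reads in OSKM (mean ± SD, n = 2) and at the floor of 1 read in both C2 libraries, at least 793-fold lower. The neighbouring Meg3, a maternally expressed imprinted noncoding RNA of the Dlk1-Dio3 cluster, fell with it and was at least 111-fold lower (adjusted p = 2.09e-06). Genes of endoderm rose: Lamb1, a laminin of basement membranes, went from 81.2 ± 77.5 to 576 ± 279.8 normalized reads (log2 fold change 3.15 ± 0.47 SE, adjusted p = 0.000368). Foxa2, an endoderm transcription factor, went from 13.2 ± 5.80 to 133 ± 116 (log2 fold change 2.96, adjusted p = 0.00317), a call that was lost without C2 replicate 1 (1.94, adjusted p = 0.0618). Pluripotency genes fell, among them Zfp42 (Rex1, a marker of naive cells), from 3309 ± 78.2 to 781 ± 186 (log2 fold change -2.10, adjusted p = 0.000172), though Zfp42 lies on chromosome 8 and had an adjusted p = 0.0515 without OSKM replicate 1.

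Of 35 naive and core pluripotency genes, 18 were called lower and 0 higher, 27 lower when adjusted over the list alone, and 16 fell in both fits (12 without chromosomes 8, X and Y). The median of that list was -0.94, but -0.20 after quantile normalization, and its adjusted p of 2.97e-06 with camera became adjusted p = 0.973 with an estimated correlation. Triml2 on chromosome 8 (-2.16) and Lefty2 (-1.64), an inhibitor of Nodal signalling, were among them, with Dppa2 (-1.07). Without OSKM replicate 1 or 2, Lefty2 had adjusted p = 0.492 and 0.376 and Dppa2 0.455 and 0.470. Pou5f1 itself, which encodes Oct4, was at 1889 ± 641 in C2 and 4032 ± 10.5 in OSKM (log2 fold change -1.14, adjusted p = 0.0401), and Sox2 was lower by a log2 fold change of -1.10 (adjusted p = 0.0246). Without OSKM replicate 1 or 2 neither was called (adjusted p = 0.771 and 0.750 for Pou5f1, 0.674 and 0.616 for Sox2), and Pou5f1 was not called with edgeR. Klf4 (-0.78, adjusted p = 0.0577) and Myc (-0.40, adjusted p = 0.415) were not called, so 2 of the 4 transduced factors fell, 3 being lower when adjusted over the list alone. The calls at Pou5f1 and Sox2 were also lost with a pseudocount of 8 and in the authors' deposited table. Reads of a transduced copy cannot be told here from those of the endogenous exons of these 4 genes. H3K27ac peaks had a median fold enrichment of 4.20 and 3.62 in the C2 libraries, against 4.49 and 4.50 in OSKM. Housekeeping and histone cluster genes were lower in C2 as well, so the falls are not shown to be particular to pluripotency genes. How far weaker enrichment in C2 adds to them was not tested.

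Of 18 endoderm genes, 7 were called higher and 0 lower, 9 higher when adjusted over the list alone, and 4 rose in both fits, with a median of 0.73 (0.86 after quantile normalization) and an adjusted p of 2.48e-05. With an estimated correlation that became adjusted p = 0.973. Gata4, a transcription factor of primitive endoderm, rose by 1.12 and Cubn, an endocytic receptor, by 0.90, Gata4 having an adjusted p = 0.203 without OSKM replicate 1 and Cubn 0.215 and 0.418 without OSKM replicate 1 or 2. Cubn was also not called with median-centred libraries or in the authors' deposited table. The histone cluster genes, which encode replication-dependent histones, had the lowest list median (-0.999, and -0.71 after quantile normalization): of 66, 44 were called lower and 0 higher, 54 lower and 3 higher when adjusted over the list alone, and 19 fell in both fits. Their adjusted p of 1.83e-06 became adjusted p = 0.973 with an estimated correlation. Of 392 zinc finger (Zfp) genes, 53 were called lower and 3 higher (62 and 3 when adjusted over the list alone), and in both fits 32 fell and 2 rose, or 12 and 2 without chromosomes 8, X and Y. Their adjusted p was 0.0360, and adjusted p = 0.996 with an estimated correlation, 0.506 after quantile normalization and 0.0808 with the lowest 25% of regions left out.

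Further lists passed, with smaller shifts or with none at the median. Among 16 housekeeping genes 5 were called lower (10 when adjusted over the list alone) and 3 fell in both fits, Rplp0 (-0.99), Eef1a1 (-1.01) and Hprt (-1.02), with a median of -0.66 that quantile normalization brought to -0.09. Without OSKM replicate 1 or 2 these 3 were lost (adjusted p = 0.187 and 0.158, 0.463 and 0.538, and 0.216 and 0.212), and they were not called in the authors' deposited table. Among 22 genes of the H3K9 methylation machinery 6 were called lower (8 when adjusted over the list alone), and Suv39h1 (-1.49), Cbx3 (-1.24), Kdm3a (-0.94) and Cbx5 (-0.93) fell in both, although the median of -0.48 turned to 0.04 after quantile normalization. Suv39h1 kept its call without each library in turn, whereas Cbx3 (0.168 and 0.245), Kdm3a (0.234 and 0.279) and Cbx5 (0.509 and 0.593) lost theirs without OSKM replicate 1 or 2, and in the authors' deposited table. Lyz2 (2.39) and Tek (1.84), a myeloid and an endothelial gene, rose among 13 endothelial and haematopoietic genes, the same pair when adjusted over the list alone, at a list median of 0.06. Of 120 olfactory receptors 2 were called higher and 1 lower (0 when adjusted over the list alone), at a median of 0.06 that is also the median of all regions. Regions at 1 read in all 4 libraries take this value (0.062) from the scaling alone, so a median of 0.06 shows no shift in either list. The adjusted p of these 4 lists were 0.0168, 0.0304, 0.0450 and 0.000735, and each became adjusted p = 0.973 with an estimated correlation. After quantile normalization none of the 4 passed (adjusted p = 0.428, 0.736, 0.184 and 0.934). The H3K9 machinery was also lost with the lowest 25% of regions left out (0.0617), and the endothelial and haematopoietic genes with another gene window (0.287) or without chromosomes 8, X and Y (0.0558).

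Among the lists that did not pass, 28 imprinted genes had 1 higher and 3 lower in both fits (1 and 6 when adjusted over the list alone). Impact (-1.98) and Zrsr1 (-1.44), both expressed from the paternal copy, fell with Meg3, and Kcnq1 rose by 1.02. In both fits Snai1 (1.29) rose and Tgfbi (-1.31) fell among 34 fibroblast genes, 3 rose and 4 fell among 23 epithelial genes (including Grhl2 1.02, Ovol2 0.98, Krt19 1.32, Marveld3 -1.78), and 1 rose and 2 fell among 18 primed pluripotency genes (Grhl2 again, Zic5 -1.57 and Dnmt3a -0.97). Tfap2c (-1.13) fell among 13 trophoblast genes. Tubb3 (-1.49), Irx3 (-1.97) and Olig1 (-1.08) fell among 20 neuroectoderm genes, the first pair on chromosome 8. Meis2 (-1.01) and Wnt3a (-0.95) fell among 20 mesoderm genes. Among 26 germline genes Stra8 rose (0.80) and Dmrtb1 (-1.59) and Zfp42 fell. Among 13 genes of the cell cycle arrest list Ccnd2 rose (1.21) and Ccnd1 (-1.08) and Mdm2 (-1.004) fell. Ccnd1, Ccnd2 and Mdm2 act against arrest, so the name of the list does not describe them. The calls at Kcnq1, Tgfbi, Grhl2, Ovol2, Dnmt3a, Tfap2c, Olig1, Meis2, Wnt3a, Stra8, Ccnd1, Ccnd2 and Mdm2 were lost without OSKM replicate 1 and without OSKM replicate 2 (adjusted p from 0.0586 to 0.649). Those at Snai1 (0.0709), Krt19 (0.258) and Tubb3 (0.0548) were lost without replicate 1 of OSKM alone, and those at Marveld3 (0.0546) and Dmrtb1 (0.112) without replicate 2 alone. Adjusted over the list alone, the counts of higher and lower members were 1 and 1 (fibroblast), 4 and 4 (epithelial), 3 and 8 (primed), 0 and 2 (trophoblast), 2 and 6 (neuroectoderm), 0 and 3 (mesoderm), 2 and 2 (germline) and 1 and 8 (cell cycle arrest). Fst (1.163), Pax7 (1.85), Rhox6 (1.38), Mesp2 (-1.11) and Ywhaz (-0.81) were called in the planned fit alone. In both fits 3 of 43 vomeronasal receptors and 3 of 34 Hox genes fell (4 and 6 lower when adjusted over the list alone). None of 30 clustered protocadherins and none of 3 genes of the 2-cell-like list was called with limma, with 1 and 0 at an unadjusted p under 0.05 and 1 and 0 called with edgeR.

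Over all H3K27ac regions 14115 of 135566 regions were called, 6493 higher and 7622 lower in C2 (46% higher). In both fits 5185 rose and 5432 fell, of which 5117 and 3540 lay outside chromosomes 8, X and Y. The share called higher differed between settings, being 69.3% in the authors' deposited table (12445 of 17947) and 20.3% with median-centred libraries (6057 of 29888), so the balance of gains and losses is open. Other large gains were at Sfi1 (at least 297-fold), a gene with related copies in the mouse genome where the place of reads is uncertain, Pex7 (at least 120-fold), Fnip2 (at least 89.9-fold) and Wdfy3 (at least 83.4-fold), and large losses were at Uty on chromosome Y (at least 105-fold) and Gm36843 on chromosome 8 (at least 102-fold). Between 4895 (without OSKM replicate 1) or 5907 (without OSKM replicate 2) and 35524 (without C2 replicate 2) or 37717 (without C2 replicate 1) regions were called when 1 library was left out, and quantile normalization left 109. Of the 51 named regions called in both fits, 19 were called without each library in turn, 29 were lost without OSKM replicate 1, 26 without OSKM replicate 2 and 48 after quantile normalization.

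**Figure D2:**
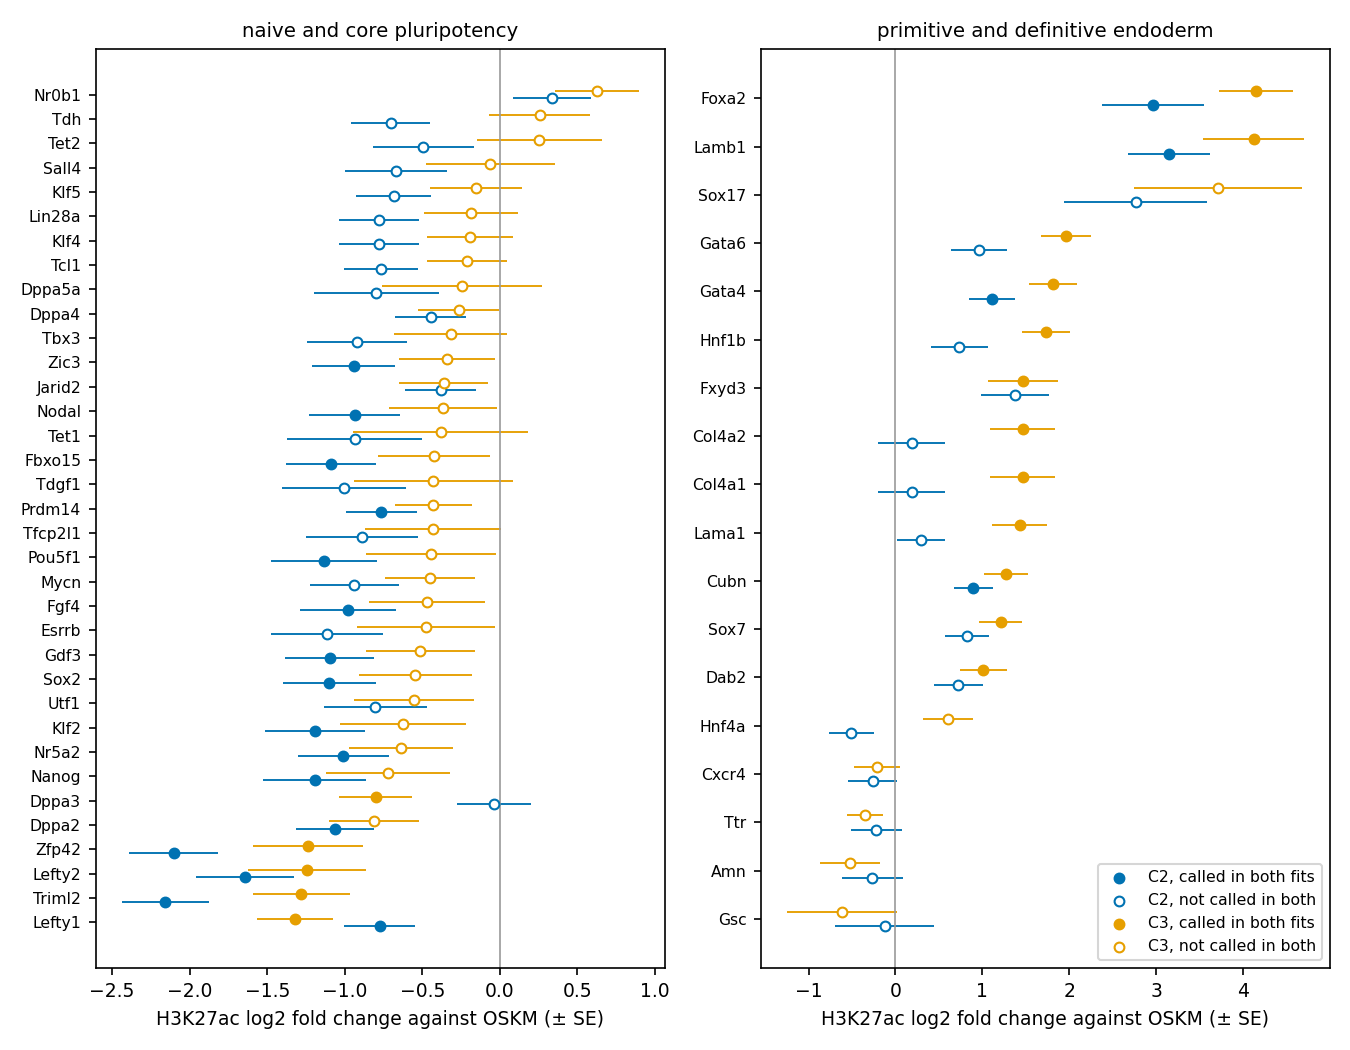
H3K27ac log2 fold change against OSKM (horizontal axis, ± SE, 2 libraries per group) of each naive and core pluripotency gene (left) and endoderm gene (right), for C2 and C3; filled points were called in both fits. The list medians were -0.94 (C2) and -0.43 (C3) on the left and 0.73 (C2) and 1.45 (C3) on the right, and after quantile normalization -0.20 and -0.20, and 0.86 and 1.43.

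The second comparison sets C3 iPS cells against OSKM iPS cells for the same mark, with the input samples differing between them. Endoderm genes rose here too: of 18, 13 were called higher and 0 lower, also when adjusted over the list alone, and 12 rose in both fits (10 without chromosomes 8, X and Y). Foxa2 went from 14.4 ± 6.31 to 276 ± 126 normalized reads (mean ± SD, n = 2; log2 fold change 4.15 ± 0.43 SE, adjusted p = 0.000335), Lamb1 by 4.12, and the primitive endoderm factors Gata6 and Gata4 by 1.96 and 1.81. The region at Gm34081 upstream of Meg3 was at the floor in both C3 libraries against 2745 ± 159.6 in OSKM, at least 949-fold lower, and Meg3 was at least 133-fold lower. Of 35 naive and core pluripotency genes, 5 fell in both fits and 0 rose (3 without chromosomes 8, X and Y; 5 lower when adjusted over the list alone), with a median of -0.43. Pou5f1 (3330 ± 1221 against 4383 ± 7.88, log2 fold change -0.45, adjusted p = 0.597), Sox2 (-0.54, adjusted p = 0.371), Klf4 (-0.19) and Myc (0.12) were not called, nor did any of these 4 have an unadjusted p under 0.05 or a call with edgeR.

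The endoderm list had a median of 1.45 (1.43 after quantile normalization) and an adjusted p of 3.31e-07 with camera, and adjusted p = 0.913 with an estimated correlation. The histone cluster genes were the other list that passed (median -0.35, adjusted p = 0.0436, but adjusted p = 0.913 with an estimated correlation and 0.437 with median-centred libraries), though none of the 66 was called with limma, 3 being lower and 1 higher at an unadjusted p under 0.05 and 0 with edgeR. Among naive genes Lefty1 (-1.32), Triml2 (-1.28), Zfp42 (-1.24) and Dppa3 (-0.80) fell, the middle pair on chromosome 8 and Zfp42 not called with edgeR. Dppa3 was not called with a replicate block or in the authors' deposited table. Without OSKM replicate 1 or 2 the adjusted p were 0.370 and 0.346 for Triml2, 0.565 and 0.549 for Zfp42, and 0.318 and 0.164 for Dppa3, and without OSKM replicate 1 that of Lefty1 was 0.148. In both fits 4 primed pluripotency genes of 18 rose and 0 fell, Krt18 (2.12), Fst (1.65), Grhl2 (1.49) and Lef1 (0.95, adjusted p = 0.233 and 0.0572 without OSKM replicate 1 or 2), with 5 higher and 1 lower when adjusted over the list alone.

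Snai1 (1.65), Pdgfra (1.52) and Vim (0.98) rose among 34 fibroblast genes and 2 fell, including Tgfbi (-1.39). Of 23 epithelial genes 3 rose, Krt18, Grhl2 and Ovol2 (1.41), and 1 fell, Marveld3 on chromosome 8 (-2.85). Of 20 mesoderm genes 5 fell and 0 rose, including Mixl1 (-2.44), a gene of the primitive streak, Tbx6 (-1.57), Wnt3a (-1.25) and Meis2 (-0.90). Neurog1 (-2.90), Olig1 (-1.14) and Tubb3 (-0.97) fell and Six3 (1.35) rose among 20 neuroectoderm genes. Tek (2.75) and Lyz2 (2.00) rose and Runx3 (-1.36) fell among 13 endothelial and haematopoietic genes. Of 28 imprinted genes 2 rose, including Kcnq1 (1.54), and 3 fell, Meg3, Zrsr1 (-1.46) and Impact (-1.44, adjusted p = 0.0896 without OSKM replicate 1). Further changes in both fits were Tfap2c (-1.62) and Gata3 (0.86) of 13 trophoblast genes, Mov10l1 (-1.72), Zfp42 and Cpxm1 (0.74) of 26 germline genes, and Gusb (-1.10) of 16 housekeeping genes. Ccnd2 rose by 1.41 and 3 fell, including Gadd45b (-1.44) and Ccnd1 (-0.87), among 13 genes of the cell cycle arrest list, Ccnd1 not being called with edgeR. The cyclins Ccnd1 and Ccnd2 act against arrest. The calls at Vim, Meis2, Tubb3, Kcnq1, Gata3, Cpxm1 and Ccnd1 were lost without OSKM replicate 1 and without OSKM replicate 2 (adjusted p from 0.0829 to 0.528). Those at Ovol2 (0.0512), Tbx6 (0.161), Wnt3a (0.0595), Six3 (0.0565), Lyz2 (0.0555) and Gusb (0.0749) were lost without replicate 1 of OSKM alone, and those at Olig1 (0.0829) and Mov10l1 (0.130) without replicate 2 alone. Adjusted over the list alone, the counts of higher and lower members were 3 and 2 (fibroblast), 4 and 1 (epithelial), 1 and 5 (mesoderm), 1 and 4 (neuroectoderm), 4 and 2 (endothelial and haematopoietic), 2 and 3 (imprinted), 1 and 1 (trophoblast), 0 and 1 (germline), 0 and 1 (housekeeping) and 1 and 3 (cell cycle arrest). Adgre1 (1.90) was called in the planned fit alone.

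Of 392 Zfp genes 6 rose and 30 fell in both fits (12 without chromosomes 8, X and Y; 25 lower and 6 higher when adjusted over the list alone). Of 120 olfactory receptors 10 rose and 0 fell, of 43 vomeronasal receptors 1 rose and 1 fell, 1 of 30 protocadherins rose and 2 of 34 Hox genes fell. Adjusted over the list alone, 5 olfactory receptors were higher, 1 vomeronasal receptor was lower and no protocadherin or Hox gene was called. None of the 22 genes of the H3K9 machinery was called with limma, with 1 higher and 2 lower at an unadjusted p under 0.05 and 1 lower with edgeR, and none of the 3 genes of the 2-cell-like list had an unadjusted p under 0.05 or a call with edgeR. Over all H3K27ac regions 24023 were called, 14415 higher and 9608 lower in C3, and in both fits 13124 rose and 8297 fell (12799 and 6323 outside chromosomes 8, X and Y). Higher regions were 60% of the calls, but 38.6% with median-centred libraries (12857 of 33272). Median centring also ended the calls at 5 of the 52 named regions called in both fits, Zfp42 among them. Other large changes were gains at Sfi1 (at least 621-fold, with the same uncertainty) and Fnip2 (at least 201-fold) and losses at Pgbd5, Kcnn1 and Anapc10 on chromosome 8 and at Otud3 (each at least 157-fold). Leaving out C3 replicate 1 or 2 gave 42393 and 44099 calls and leaving out OSKM replicate 1 gave 14797, while quantile normalization left 46. Of the 52 named regions called in both fits, 31 were called without each library in turn, 19 were lost without OSKM replicate 1, 13 without OSKM replicate 2 and 47 after quantile normalization.

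The H3K27ac changes of C2 and C3 against OSKM overlapped. In both fits 4678 regions rose in both lines, 90.2% of those that rose in C2, where independent changes would give 502 and simulated libraries that share OSKM but hold no change gave 0 by the same rule. Likewise 3009 fell in both, 55.4% of those that fell in C2 (332 if independent, 0.05 in the simulations), and 2 moved in opposite directions. Counting those calls outside chromosomes 8, X and Y, 4615 rose and 1666 fell in both lines, 90.2% and 47.1% of those in C2 (523 and 179 if independent, 0 and 0.05 in the simulations). The Gm34081 region, Meg3, Impact, Zrsr1 and Zfp42 fell in both lines, and Foxa2, Lamb1, Gata4, Tek and Lyz2 rose in both. Both comparisons use the same pair of OSKM libraries, so part of this overlap of calls above independence can come from them, and 2 libraries cannot be split to count it. A trait of the OSKM line itself would also appear in both comparisons. Simulations without change cannot tell such a trait from a change common to C2 and C3. The covariance of the log2 fold changes of both lines was 1.39, against 0.160 in the simulations without change, whereas 59.5% of regions had the same sign, against 66.6%. Regions at 1 read in all 4 libraries of a comparison (22.8% for C2, 24.9% for C3) take a value fixed by the scaling. That value is 0.062 for C2 and -0.063 for C3, so regions at the floor in both comparisons count as opposite signs. The share with the same sign therefore cannot measure shared change.

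Directly between C2 and C3, 59 H3K27ac regions differed in both fits. Pde7a (9.90 ± 5.14 in C2 against 202 ± 45.8 normalized reads in C3, mean ± SD, n = 2; log2 fold change -4.28, adjusted p = 8.80e-13), which encodes a phosphodiesterase of cyclic AMP, and Nlrc5 on chromosome 8 (-5.29), a regulator of MHC class I genes, were lower in C2. Cdyl2 on chromosome 8 (4.70) and Gm12216 (5.33) were higher in C2. Uty on chromosome Y was at the floor in C2, at least 85.3-fold lower. Of the 6 named regions called in both fits, 2 were not called with a pseudocount of 8. Without regions at 1 read in all libraries 3 were not called, and with quantile normalization 6 were not. Cdyl2 and Pde7a stayed called without each library in turn, whereas Gm12216 was lost without C2 replicate 2 (adjusted p = 0.292), and Uty and Nlrc5 without C3 replicate 1 (0.137 and 0.261). Pou5f1 (-0.65, adjusted p = 0.791), Sox2 (-0.52, adjusted p = 0.791), Klf4 (-0.55, adjusted p = 0.699) and Myc (-0.48, adjusted p = 0.651) were not called, and none of these 4 had an unadjusted p under 0.05 or a call with edgeR.

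Endoderm genes tended lower in C2 than in C3 as a list (median -0.63, adjusted p = 0.00680 with camera, and adjusted p = 0.957 with an estimated correlation). Of 18 members 2 were called lower, Col4a1 and Col4a2, which share 1 region on chromosome 8 (log2 fold change -1.24, adjusted p = 0.0126), 6 were lower when adjusted over the list alone, and 0 were called in both fits. The histone cluster genes were also lower as a list (median -0.57, adjusted p = 5.00e-06, and adjusted p = 0.957 with an estimated correlation), with 2 of 66 called lower and 5 when adjusted over the list alone. Tbx6 (1.72) among mesoderm genes and Kcnq1ot1 (-1.45) among imprinted genes were called in the planned fit alone, as were Nanos3 (5.00), Gm31955 (-4.32) and Prelid2 (-3.99) among the largest changes. Olfactory receptors (7 lower), Zfp genes (1 higher, 2 lower), Hox genes (2 lower) and vomeronasal receptors (1 lower) held the other calls of that fit. Members of the naive pluripotency, primed pluripotency, fibroblast, epithelial, trophoblast, neuroectoderm, endothelial and haematopoietic, 2-cell-like, germline, H3K9 machinery, housekeeping, cell cycle arrest, transduced factor and protocadherin lists were not called. Over all 22 lists (991 members) 0 were called in both fits with limma, beside 105 with an unadjusted p under 0.05 and 9 with edgeR.

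In the planned fit 2723 regions were called between C2 and C3, 730 higher and 1993 lower in C2, but 28 and 31 in both fits, 59 being also the number with the lowest 25% of regions left out. With a replicate block 18665 were called, and libraries of the same number correlated at 0.35. No pairing of replicates is labelled, so how many regions differ between these lines stays open. Higher regions were 26.8% of the planned calls and 73% of those in the authors' deposited table (1774 of 2430), so no balance can be given. The count was 239 without C2 replicate 2, 301 without C3 replicate 1 and 9560 without C2 replicate 1, and 31 after quantile normalization.

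For H3K9me3, the comparison of C2 with OSKM asks whether repressive chromatin differs between these lines. The neighbouring zinc finger genes Zfp12 and Zfp316 on chromosome 5 rose: Zfp12 (143242860 to 143249227) was at the floor in OSKM and at 752 ± 165 normalized reads in C2 (mean ± SD, n = 2), at least 316-fold higher (adjusted p = 8.47e-05), and Zfp316 rose by a log2 fold change of 8.12. Several imprinted genes changed: Zrsr1 was at least 43.7-fold higher, Igf2r, a receptor that clears IGF2, rose by 5.99, Impact by 5.52 and Grb10, a growth inhibitor, by 1.49, while Rtl1, a retrotransposon-derived gene of the Dlk1-Dio3 cluster, fell from 634 ± 77.2 to 137 ± 4.28 (log2 fold change -2.20, adjusted p = 0.00173). Losses were largest at Rn18s-rs5 and AY036118 on chromosome 17, which resemble ribosomal RNA genes present in many copies (at least 1409-fold and 551-fold lower), so that the place of those reads is uncertain. Gm33272 on chromosome Y and Mid1 on X, which lie by the region the sex chromosomes share, were at least 858-fold and 456-fold lower in C2, with the same uncertainty.

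Of 24 imprinted genes with an H3K9me3 region 3 rose and 1 fell in both fits, with 5 higher and 4 lower when adjusted over the list alone. This list scores Igf2r at its strongest region (-0.06, adjusted p = 0.919), so the Igf2r region that rose (chromosome 17, 12742091 to 12744691) is not among those 3. Of 168 Zfp genes 3 rose and 6 fell (3 and 1 without chromosomes 8, X and Y; 9 higher and 15 lower when adjusted over the list alone). Smarcad1 (3.86), a chromatin remodeller, and Laptm5 (1.01), a gene of blood cells, rose, and Dpep3 on chromosome 8 (-2.07), a germline gene, and 1 of 7 histone cluster genes fell. Pou5f1 (-0.67, adjusted p = 0.0923) and Myc (-0.35, adjusted p = 0.247) were not called. No member of the naive pluripotency, primed pluripotency, fibroblast, epithelial, endoderm, trophoblast, neuroectoderm, mesoderm, 2-cell-like, H3K9 machinery, housekeeping, cell cycle arrest, olfactory receptor, vomeronasal receptor, protocadherin or Hox lists was called. Of 24 protocadherins 12 were lower when adjusted over the list alone (median -1.17), as were 3 of 5 naive pluripotency genes. No list of 19 passed with camera, 3 having an unadjusted p under 0.05, though vomeronasal receptors did after quantile normalization (adjusted p = 0.0470), and over all lists 17 of 504 members were called with limma and 17 with edgeR, beside 139 with an unadjusted p under 0.05.

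Over all H3K9me3 regions 808 of 68845 regions were called, 175 higher and 633 lower in C2, and in both fits 64 rose and 624 fell, of which 64 and 157 lay outside chromosomes 8, X and Y. H3K9me3 peaks had a median fold enrichment of 3.90 and 4.18 in the C2 libraries, against 4.41 and 4.48 in OSKM. Reads in regions numbered 4455379 and 3412599 in C2, against 7118324 and 8548902 in OSKM. How far stronger enrichment in OSKM adds to the losses was not tested. Higher regions were 21.7% of the calls and 34.7% in the authors' deposited table (1174 of 3379). The count rose to 9694 without C2 replicate 1 and 8315 without C2 replicate 2, and dropped to 14 when the fit left out chromosomes 8, X and Y, which ended the calls at Igf2r, Smarcad1, Zrsr1, Impact, Grb10 and Laptm5. Laptm5 was also lost without OSKM replicate 1 (adjusted p = 0.123), and 8 of the 16 named regions called in both fits were lost after quantile normalization.

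C3 iPS cells were compared with OSKM iPS cells in H3K9me3 as well, with inputs again differing. Zfp12 rose from the floor to 1078 ± 3.12 normalized reads in C3 (mean ± SD, n = 2), at least 409-fold, and Zfp316 rose by 8.44. Zrsr1 was at least 54.5-fold higher, Igf2r rose by 6.04 and Impact by 5.79. Pou5f1 fell from 542 ± 58.6 to 285 ± 87.7 (log2 fold change -0.95 ± 0.15 SE, adjusted p = 4.37e-06), at a short region inside the gene (chromosome 17, 35505998 to 35506575), and Esrrb, a nuclear receptor of naive cells, fell by 1.18. Cdh1, the epithelial cadherin, fell by 4.00 on chromosome 8, and Snai1, a repressor of Cdh1, by 2.86.

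Of 5 naive pluripotency genes with an H3K9me3 region 3 fell (Esrrb, Pou5f1 and Jarid2 at -0.77), also when adjusted over the list alone. Myc fell by 1.46, so both transduced factors with a region, Pou5f1 and Myc, were lower. Of 168 Zfp genes 43 fell and 6 rose in both fits (35 and 6 without chromosomes 8, X and Y; 62 lower and 11 higher when adjusted over the list alone). Of 24 imprinted genes 3 rose and 3 fell, including Rtl1 (-2.23) and Nnat (-1.10), with 3 higher and 9 lower when adjusted over the list alone; the list again scores Igf2r at its strongest region, lower in the planned fit alone (-0.82). Krt8 (0.92) rose and 2 fell, including Cdh1, among 5 epithelial genes, Zeb1 (-0.97) and Snai1 fell among 13 fibroblast genes, and Ascl2 (-2.80) and Esrrb fell among 5 trophoblast genes. Cubn (1.23) rose of 2 endoderm genes, Otx1 (-1.60) fell of 3 neuroectoderm genes, and Laptm5 (0.78) rose and Runx3 (-1.02) fell of 6 endothelial and haematopoietic genes. Sp110 (0.59) rose of 9 genes of the 2-cell-like list, Dpep3 (-1.67) and Stk31 (-0.55) fell of 14 germline genes, Atf7ip (-0.63) and Kdm3a (-1.20) fell of 6 genes of the H3K9 machinery, Cdkn2c (-0.78) fell of 4 genes of cell cycle arrest and 1 of 7 histone cluster genes fell. Among the primed pluripotency, mesoderm, housekeeping and Hox lists no member was called with limma or edgeR, and 2 Hox genes had an unadjusted p under 0.05. Adjusted over the list alone, the counts of higher and lower members were 1 and 5 (fibroblast), 0 and 5 (germline), 0 and 5 (H3K9 machinery) and 1 and 2 (cell cycle arrest). Fn1 (-1.61), Runx1 (1.06), Six3 (0.72), Zscan5b (-0.79), Fkbp6 (-2.21) and Atrx (-3.16) were called in the planned fit alone.

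Of 24 clustered protocadherins, cell adhesion genes of neurons, 7 rose and 3 fell, also when adjusted over the list alone. The list's test was in the higher direction (adjusted p = 0.0436, but adjusted p = 0.730 with an estimated correlation, 0.124 after quantile normalization, 0.671 with another gene window and 0.0590 without chromosomes 8, X and Y), although its median was -0.15. Olfactory and vomeronasal receptors passed as lists in the higher direction at medians of 0.09 and 0.09 (adjusted p = 0.00129 for each, and adjusted p = 0.316 with an estimated correlation). Their called members were mostly lower: in both fits 1 rose and 4 fell of 98 olfactory receptors (1 and 5 when adjusted over the list alone), and 2 rose and 5 fell of 96 vomeronasal receptors (4 and 7 when adjusted over the list alone).

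Over all H3K9me3 regions 6821 were called, 1594 higher and 5227 lower in C3, and in both fits 860 rose and 3760 fell (850 and 2806 outside chromosomes 8, X and Y). The median fold enrichment of H3K9me3 peaks was 4.105 and 4.255 in the C3 libraries, against 4.41 and 4.48 in OSKM. Whether stronger enrichment in OSKM adds to these losses was not tested either. Higher regions were 23.4% of the calls, 34.3% in the authors' deposited table (2317 of 6747) and 10.3% after quantile normalization (13 of 126). With that normalization on regions above 1 read in each library they were 41.7% (1857 of 4453). Other large changes were gains at Cd36 (4.70), a fatty acid transporter, and Tgfbr3 (4.02), and losses at Rn18s-rs5 (at least 1665-fold), AY036118 (at least 650-fold), a region without a gene on chromosome 15 (75086120 to 75087048, at least 568-fold) and 2700038G22Rik (-6.12). The count was 3440 without OSKM replicate 1 and 3571 without OSKM replicate 2. Of the 34 named regions called in both fits 26 were called without each library in turn. Otx1 and Laptm5 were among those lost without OSKM replicate 1 (adjusted p = 0.141 and 0.0571), and Jarid2, Stk31, Atf7ip, Kdm3a and Cdkn2c among those lost without OSKM replicate 2 (0.171, 0.171, 0.0946, 0.519 and 0.107), and 29 were lost after quantile normalization.

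**Figure D3:**
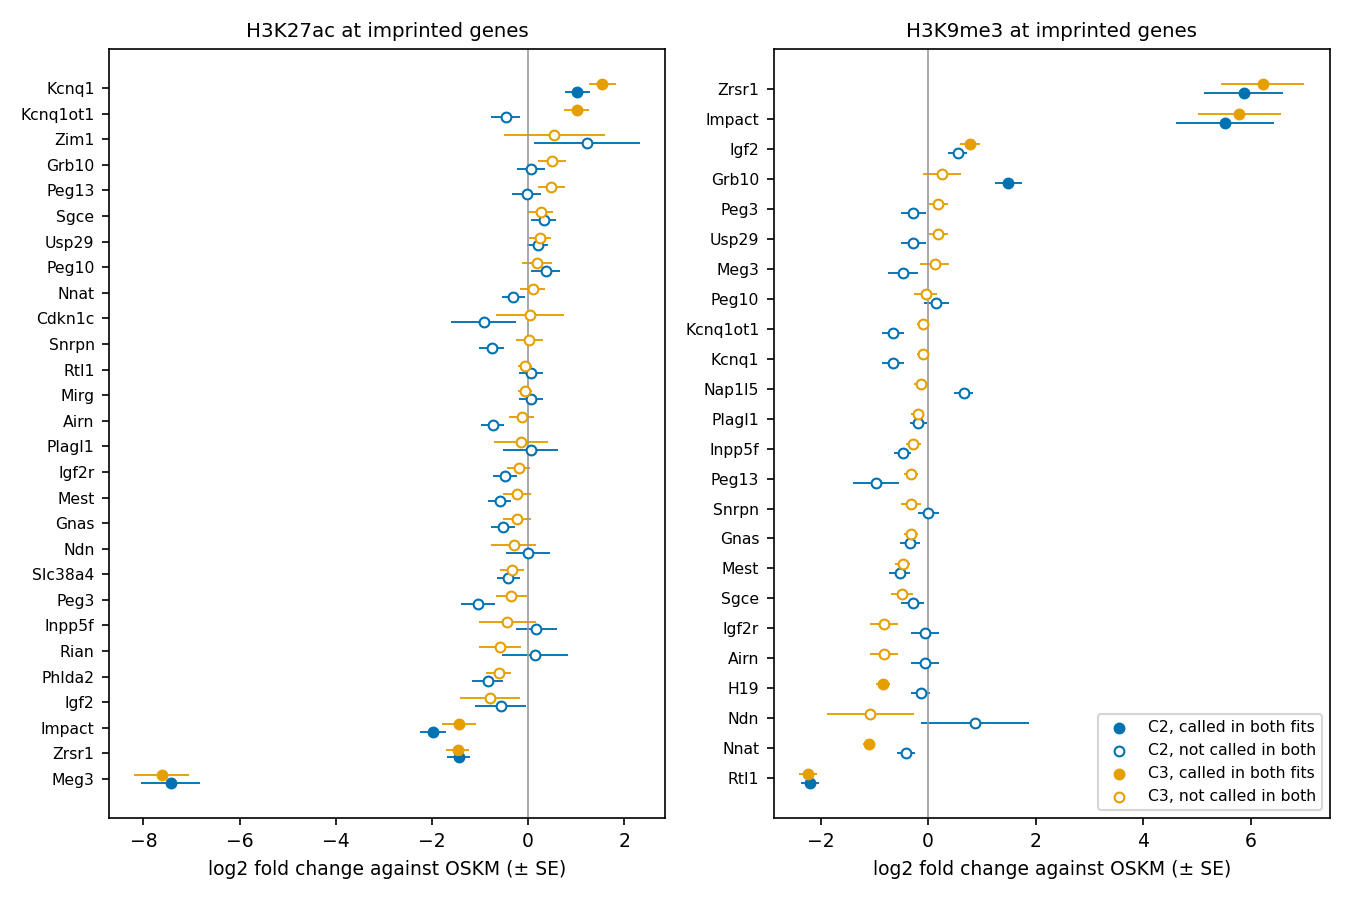
Log2 fold change against OSKM (horizontal axis, ± SE, 2 libraries per group) of each imprinted gene at its strongest region, in H3K27ac (left) and H3K9me3 (right), for C2 and C3; filled points were called in both fits. Meg3 is lowest in H3K27ac (-7.43 in C2 and -7.62 in C3), and Zrsr1 and Impact are low in H3K27ac and the highest points in H3K9me3, where the Igf2r region named above is not plotted (5.87 and 5.52 in C2, 6.23 and 5.79 in C3). The values of Meg3, and those of Zrsr1 in H3K9me3, are fitted against groups at the floor and depend on the pseudocount: the bounds are at least 111-fold and 133-fold lower, and at least 43.7-fold and 54.5-fold higher.

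Changes of H3K9me3 were also shared by C2 and C3. In both fits 48 regions rose in both lines, among them Zfp12, Zfp316, Igf2r, Zrsr1 and Impact, where independent changes would give 0.799 and simulated libraries that share OSKM but hold no change gave 0.1 on average by the same rule. Likewise 500 fell in both, among them Rtl1 and Rn18s-rs5, with 34.1 if independent and 0.05 in the simulations, and 3 moved in opposite directions. Of these calls all 48 of those that rose, but 134 of those that fell, lay outside chromosomes 8, X and Y (7.68 of the latter if independent, 0.05 in the simulations). In a fit made without those chromosomes, however, 14 regions were called between C2 and OSKM, and the C2 calls at Igf2r, Zrsr1 and Impact ended. As for H3K27ac, the shared OSKM libraries can add to this overlap of calls, and so can a trait of the OSKM line itself. The covariance of the log2 fold changes was 0.379, against 0.124 in the simulations, and 75.8% of regions had the same sign, against 66.7%. Regions at 1 read in all 4 libraries (12.5% for C2, 12.4% for C3) again take a fixed value, 0.339 for C2 and 0.207 for C3. Regions at the floor in both comparisons thus count as the same sign, and this share cannot measure shared change either.

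Between C2 and C3, the H3K9me3 regions with the largest difference lay on the sex chromosomes. Ddx3y, an RNA helicase gene of chromosome Y, was at 578 ± 46.7 normalized reads in C3 (mean ± SD, n = 2) and at the floor in C2, at least 173-fold lower (adjusted p = 1.86e-21). Gm33272 was at least 297-fold lower, Mid1 at least 230-fold lower, and regions of chromosome Y without a gene at 258058 and 953021 were at least 166-fold and 96.0-fold lower. These 5 kept their call without each library in turn. All 106 called regions of chromosome Y were lower in C2.

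Of the lists, vomeronasal receptors alone had members that changed in both fits, 2 of 96 being higher in C2. Named members called in the planned fit alone were Myc (1.11), Ascl2 (2.21), Otx1 (1.56), Grb10 (1.31) and Nap1l5 (0.80), all higher in C2, as were 2700038G22Rik (4.41), Kcnq1 (3.78) and Rrp15 (3.75) among the largest changes, while Pou5f1 was not called (0.30, adjusted p = 0.755). Zfp genes had 5 of 168 higher (11 when adjusted over the list alone) and histone cluster genes 1 of 7 lower in that fit. The naive pluripotency, primed pluripotency, fibroblast, epithelial, endoderm, mesoderm, endothelial and haematopoietic, 2-cell-like, germline, H3K9 machinery, housekeeping, cell cycle arrest, olfactory receptor, protocadherin and Hox lists had no member called in it. No list of 19 passed with camera, 3 having an unadjusted p under 0.05. Over all lists 14 of 504 members were called with limma and 18 with edgeR, beside 89 with an unadjusted p under 0.05.

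In the planned fit 403 regions were called between C2 and C3, 250 higher and 153 lower in C2 (62.0% higher, against 37.4% of 123 after quantile normalization and 50.1% of 685 in the authors' deposited table), and in both fits 24 and 46, or 24 and 5 outside chromosomes 8, X and Y. The count was 204 without C2 replicate 2, 262 without C3 replicate 2, 635 without C3 replicate 1 and 2607 without C2 replicate 1.

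The HA comparison asks where the artificial factors of C2 were bound at day 20. Peaks in both C2 libraries and in neither Empty library made 2846 sites with a median length of 523 bp, of which 802 (28.2%) overlapped a gene and 1132 (39.8%) lay within 10000 bp of 1. By the authors' fold enrichment, averaged over both libraries, the strongest site lay on chromosome 10 (72296955 to 72297299) outside any gene, at 9.85-fold. Within genes the strongest were at Adam9 (chromosome 8, 25001929 to 25003206, 9.37-fold), a metalloprotease, Tbc1d22a (9.34-fold), Rgs6, a regulator of G-protein signalling (9.20-fold), and Gm40293 (8.86-fold). Other sites among the top 10 lay outside genes on chromosomes 5, 7, 9 and 13. Single Empty libraries held peaks of up to 28.0-fold and 38.0-fold, against 21.3-fold and 21.05-fold in C2. The median fold was 5.90 and 5.56 in Empty and 5.92 and 5.93 in C2. The folds of the named sites thus lie within the range of the antibody background and do not mark them as strongly bound. Of the naive pluripotency and fibroblast lists, Meox2 alone, a mesodermal homeobox gene, lay within 10000 bp of a site (chromosome 12, 37158340 to 37160018, 6.86-fold).

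**Figure D4:**
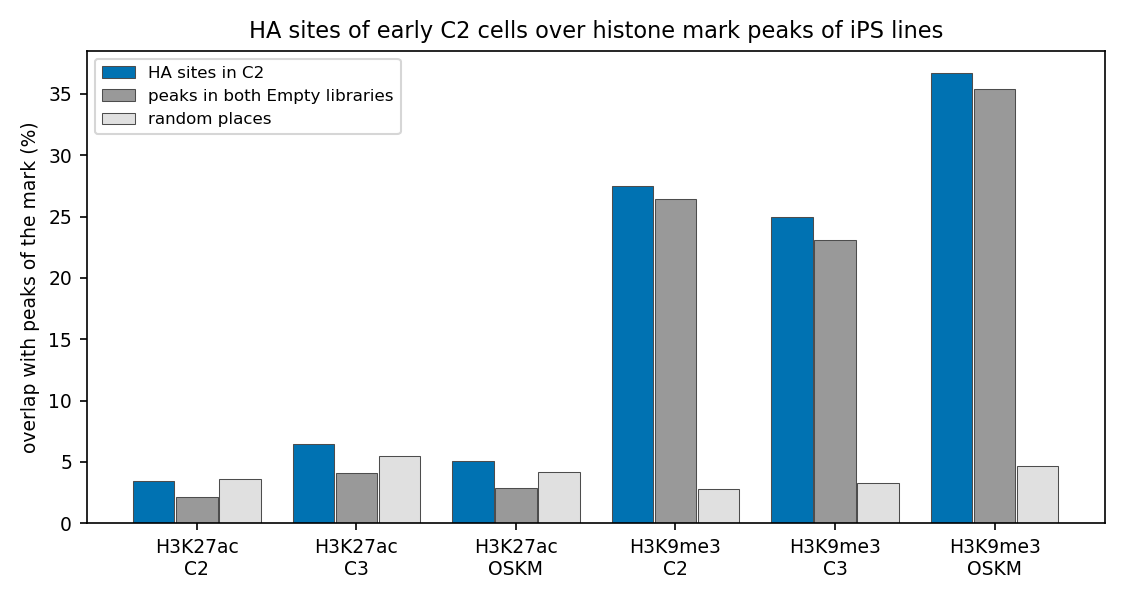
Share of HA sites of C2, of peaks found in both Empty libraries and of random places (vertical axis, percent) that overlap peaks found in both libraries of each histone group (horizontal axis). H3K9me3 peaks of OSKM overlapped 36.7% of HA sites, 35.4% of Empty peaks and 4.69% of random places.

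Part of the HA sites overlapped H3K9me3 peaks of the iPS lines, and so did part of the peaks of the Empty cells. HA sites leave out regions with an Empty peak, but the 2327 Empty peaks keep those with a C2 peak (834 had none). A difference between the sets can therefore come from this unequal filter. H3K9me3 peaks of C2 overlapped 27.5% of HA sites and 26.4% of Empty peaks (p = 0.396, adjusted p = 0.396, Fisher's exact test over peaks), those of C3 24.98% and 23.1% (p = 0.117, adjusted p = 0.175), and those of OSKM 36.7% and 35.4% (p = 0.352, adjusted p = 0.396), beside 2.75%, 3.30% and 4.69% of random places. H3K27ac peaks overlapped more HA sites than Empty peaks in the 3 lines, 3.48% and 2.11% for C2 (p = 0.00327, adjusted p = 0.00653), 6.43% and 4.08% for C3 (p = 0.000192, adjusted p = 0.000577) and 5.09% and 2.88% for OSKM (p = 5.50e-05, adjusted p = 0.000330), all by the same exact test, beside 3.63%, 5.51% and 4.16% of random places. The number of sites was 33097 without HA_C2 replicate 1 and 8447 without HA_C2 replicate 2, and 42.5% of the 12376 peaks of C2 replicate 1 were overlapped by C2 replicate 2, beside 37.5% of the 10666 peaks of Empty replicate 1. With the same number of strongest peaks taken from each library there were 975 sites in C2, and 690 regions with peaks in both Empty libraries and neither C2 library. With stricter peaks the H3K9me3 overlap did exceed that of Empty peaks, at 26.7% and 20.2% for C2 (p = 0.000311), 25.4% and 18.5% for C3 (p = 9.75e-05) and 36.6% and 26.7% for OSKM (p = 6.51e-07, Fisher's exact test).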

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

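The tests of chromosomes 8 and Y and of the imprinted regions were chosen after their results were seen. Regions and lists below are given because a direct test between the C2 and C3 lines found a difference.

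In H3K27ac, the log2 fold change of C2 against C3 was 5.33 at Gm12216 and 4.70 at Cdyl2, and -5.29 at Nlrc5 and -4.28 at Pde7a. Where C2 was at the floor the fitted values depend on the pseudocount, so each is given with its bound: in H3K27ac -7.03 at Uty (at least 85.3-fold lower), and in H3K9me3 -8.88 at Gm33272 (at least 297-fold), -8.50 at Mid1 (at least 230-fold), -8.10 at Ddx3y (at least 173-fold), and -8.04 and -7.25 at the regions of chromosome Y without a gene (at least 166-fold and 96.0-fold). As lists tested with camera, endoderm genes had a median H3K27ac log2 fold change of -0.63 and histone cluster genes of -0.57, with adjusted p = 0.957 for each with an estimated correlation.

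Both marks were higher along chromosome 8 in OSKM than in the lines made without Oct4. Subtraction of the shared input does not account for it, since the pileup, which the input does not reduce, was higher in the lowest OSKM library than in the highest C2 library by 0.416 (H3K27ac) and 0.279 (H3K9me3) on the log2 scale. Nor do a few strong regions, since both OSKM libraries lay above all others in 12 of 13 and 13 of 13 bins of 10 Mb (92.3% or more), against 33 of 252 and 30 of 256 bins elsewhere. An extra copy of chromosome 8 in the OSKM cells is a candidate explanation that stays open: the pileup was higher by 0.476 and 0.302, between 0 and the 0.585 that an extra copy would give in every cell, and no count of chromosomes is at hand. Region values went further than 0.585, with H3K27ac medians of -1.33 (C2) and -1.04 (C3), as did Zfp42 (-2.10 in C2) and Cdh1 (H3K9me3, -4.00 in C3). Some regions were at 1 read in a library that had called a peak there, as subtraction of control reads could produce. Subtraction can enlarge a fold between lines, so these region values cannot decide for or against an extra copy.

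Chromosome Y was close to the floor in the C2 iPS libraries. Lower depth does not account for it, since the highest share of H3K9me3 reads on Y in C2 was 0.270 of the lowest share in C3 and OSKM. A line with a pair of X chromosomes would have about 1 log2 unit more pileup on X, but C2 differed by -0.18 (H3K27ac) and -0.0273 (H3K9me3). Loss of Y in the C2 line may account for it, as a hypothesis: HA peaks of the earlier C2 cells lay on Y at 1.95% and 1.98%, like the 2.04% and 2.12% of the Empty cells. HA peaks are near the background, and whether they come from the same clone as the iPS line is not labelled, so a mixed-up sample stays open.

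Of 28 imprinted genes 3, Meg3, Impact and Zrsr1, had less H3K27ac in both C2 and C3 than in OSKM, and Impact and Zrsr1 had more H3K9me3, while Kcnq1 rose in H3K27ac and the list did not pass with camera. Subtraction of the input does not account for Meg3, since the region upstream of it held 4 and 2 called peaks in the OSKM libraries and 0 in each C2 library, which share their input. Scaling does not account for Meg3 either, at least 111-fold (C2) and 133-fold (C3) lower, whose fitted log2 fold change, which depends on the pseudocount, was 7.28 or larger in size under 5 scalings and tools. Over all 3 genes the smallest size, 0.997 at Zrsr1, missed its bound of 1, and Impact passed it by less than its SE in C3 after quantile normalization (-1.33, or 0.936 in size less 1 SE), so scaling stays open for both, though all 30 values were below 0 (the tests of Meg3 and Impact alone were added after that result). A difference in imprinting between lines may be the source, as may a difference between the parent cells of each line, which was not tested.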

How the results depend on the processing

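The settings with edgeR, with regions at 1 read left out, without chromosomes 8, X and Y, and with equal numbers of HA peaks were chosen after the data were seen, the others before. Numbers are regions called unless said otherwise, and the cause was not tested except where given.

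H3K27ac, C2 against OSKM (14115): 9040 with a pseudocount of 8, 29888 with median-centred libraries, 109 with quantile normalization, 7118 with that normalization on regions above 1 read in each library, 22617 at an adjusted p under 0.1 and 4895 to 37717 without a library. C3 against OSKM (24023): 46 and 18134 with the quantile settings and 14797 to 44099 without a library. C2 against C3 (2723): 18665 with a replicate block, 16 with a pseudocount of 8, 59 without the lowest 25% of regions, 31 and 135 with the quantile settings, 19 without regions at 1 read in all libraries and 239 to 9560 without a library. H3K9me3, C2 against OSKM (808): 3650 with the block, 20 with a pseudocount of 8, 1728 without the lowest 25%, 262 with median-centred libraries, 203 and 500 with the quantile settings, 3379 in the authors' deposited table, 1768 without regions at 1 read in all libraries, 14 without chromosomes 8, X and Y, 1615 without regions at 1 read where that library called a peak, 2338 at an adjusted p under 0.1 and 928 to 9694 without a library. C3 against OSKM (6821): 126 and 4453 with the quantile settings, 4511 without chromosomes 8, X and Y, 3712 with a log2 fold change of at least 1 and 3440 to 10045 without a library. C2 against C3 (403): 1188 with the block, 28 with a pseudocount of 8, 70 without the lowest 25%, 123 and 55 with the quantile settings, 685 in the authors' deposited table, 54 without regions at 1 read in all libraries, 67 without chromosomes 8, X and Y, 42 without regions at 1 read where a peak was called, 721 at an adjusted p under 0.1 and 204 to 2607 without a library.

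Part of this spread follows from the regions at 1 read: quantile normalization left 31101, 33933 and 31700 H3K27ac regions and 8754, 8641 and 9145 H3K9me3 regions with no spread, and the prior degrees of freedom of limma were then 0.892, 0.955, 0.935, 0.881, 0.864 and 0.886, against 17.2, 9.57, infinite, 6.64, 47.7 and 65.3 in the planned fits. They were also infinite without any 1 library, where the lone sample is assumed to vary like the other group. Block counts in the other comparisons were 13316 and 26071 (H3K27ac) and 7421 (H3K9me3). With the block, 5 of the 194 named regions called lost their call. The correlation of libraries of the same number was -0.07, -0.05 and 0.35 in H3K27ac and -0.01, 0.02 and 0.13 in H3K9me3, so a pairing of replicates is not established. Gene lists called fell from 15 to 0 with an estimated correlation, a setting that could hardly call any list with 2 libraries per group. In H3K27ac the 8 lists of C2 against OSKM became 4 with the block, 4 with quantile normalization and 6 without the lowest 25%, the 2 of C3 against OSKM became 1, 4 and 3, and the 2 of C2 against C3 became 4 with each. In H3K9me3, C2 against OSKM had 0 lists, but 1 with the block or quantile normalization.

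Of the 194 named regions called, 0 turned direction under any setting; 178 were not called with quantile normalization, 54 with a pseudocount of 8, 53 in the authors' deposited table, 29 without the lowest 25%, 15 with median-centred libraries, 5 with edgeR and 61 and 52 without OSKM replicate 1 or 2. Uncalled values that turned were, in H3K27ac, Myc of C2 against OSKM (0.0129 with either quantile setting, -0.91 to 0.11 without a library), Myc of C3 against OSKM (-0.21 median-centred, -0.0629 to 0.30 without a library), Klf4 of C3 against OSKM (-0.43 to 0.0446 without a library) and Myc of C2 against C3 (-1.002 to 0.0353 without a library), and in H3K9me3 Pou5f1 of C2 against C3 (-0.0383 to 0.63 without a library).

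HA sites (2846) were 1150 with stricter peaks and 1525 with reciprocal overlap, fewer by construction, 5146 without the Empty filter, 975 with equal numbers of peaks and 3310 to 33097 without a library. Over the stricter peaks, H3K9me3 overlapped 26.7% (C2), 25.4% (C3) and 36.6% (OSKM) of sites against 20.2%, 18.5% and 26.7% of Empty peaks, which passed Fisher's exact test (p = 0.000311, 9.75e-05 and 6.51e-07). The mean share of peaks overlapped by the other replicate was 57.7% to 84.8% in the histone groups and 10.4% to 27.3% in the HA groups over the settings. The HA libraries kept 1629753 to 3896935 tags, which limits their precision.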

Other observations

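The test of both marks together was written before its result was seen. The H3K27ac values below come from regions that overlap H3K9me3 regions outside chromosomes 8, X and Y, except that those of named genes come from the strongest H3K27ac region of the gene.

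Regions where H3K9me3 rose in both C2 and C3 held no common loss of H3K27ac. These 48 regions were overlapped by 26 H3K27ac regions, whose median H3K27ac log2 fold change was 0.18 (C2) and 0.33 (C3) against OSKM. In C3, 9 of the 26 rose and 3 fell in H3K27ac. Impact and Zrsr1 differed from this, with more H3K9me3 and less H3K27ac in both lines, whereas Igf2r, with more H3K9me3 in both (5.99 and 6.04), was not called at its strongest H3K27ac region (-0.48 and -0.20). Where H3K9me3 fell in both lines (134 regions, overlapped by 58 H3K27ac regions), the H3K27ac medians were -0.47 and -0.15.

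The hypothesis that H3K27ac is lower where H3K9me3 is higher would have needed a median of -0.5 or lower in C3. At 0.33 the result was contrary to it, though H3K27ac regions at the floor in OSKM could not fall and were not counted apart. The 850 regions where H3K9me3 rose in C3 were overlapped by 134 H3K27ac regions. Of these 134, 44 rose and 9 fell in H3K27ac (32.8% and 6.72%), against 8.89% and 2.76% of all 11446 H3K27ac regions that overlapped an H3K9me3 region. Where H3K9me3 fell in C3 (2806 regions, overlapped by 1609 H3K27ac regions), 142 of the 1609 rose and 122 fell in H3K27ac (8.83% and 7.58%). These shares were not tested against each other. Both marks of C3 had input samples other than those of OSKM. An input difference could therefore move both marks together in C3, and the C3 median and shares cannot be separated from it.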
